A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 8 samples.

How the data were processed

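Libraries were made from Synechococcus elongatus PCC7942, wild type and rel-, at subjective dawn and subjective dusk in constant light, with 2 libraries per group and 8 in all. Per the labels' protocols, external RNA standards went in at extraction, ribosomal RNA was depleted, and stranded libraries were sequenced on an Illumina HiSeq instrument. Bowtie 0.12.7 is named in the submitters' processing notes, with no role stated. The genome build, annotation, counting tool and treatment of reads that match several places are not given in the sources used here.

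The authors deposited 1 table with 2715 genes and 8 columns. In the column of wild type dawn replicate 1 the deposited values are whole-number counts per gene. The other 7 deposited columns are a signal that looks like a count per gene times 1 constant per library, from the values: all 2715 values of each were whole multiples of the column's constant, within a tolerance of 0.001 of a step. The constants were 0.737 for the other wild type dawn library, 1.21 and 1.38 for wild type dusk, 2.93 and 3.37 for rel- dawn, and 2.60 and 3.67 for rel- dusk. They may come from the external standards, which no header states. Although all values were whole multiples, these columns were not treated as recovered counts, because few low values exist. This was a choice, and a count test was not ruled out by the values. No count test was used and the planned count-based alternatives were not run. The reads obtained by dividing by the constants, 6559147 to 12376534 per library, gave the depth, the reads of rel, the comparison of replicates and the weighing of explanations in the closing part; no gene was tested on them. The mutant columns carry another gene symbol than the sample titles; they were matched by replicate number and time point, and no other genotype is in the table. Libraries of 1 group differed beyond sampling noise, with chi-square per degree of freedom of 29.3 to 117, so none was counted as a duplicate.

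Tests were made with limma 3.58.1 in R 4.3.3 on log2(value + 20), without trend or robust fitting, in a model of 4 group means over all 8 libraries, with 4 residual degrees of freedom. Pooling of the spread over genes raised these to 35.8 in the main fit, on which its p-values rest. The SE of a log2 change comes from this spread, pooled over the 4 groups and over genes. For a given gene it is therefore the same in every comparison of 2 groups. The pseudocount of 20 is 1 digit of a hundredth part of the median value above 0. Genes with a mean above 200 were tested, 2539 of 2715, and p-values were two-sided and adjusted by Benjamini-Hochberg over them, with a threshold of 0.05. Fold changes are on the log2(value + 20) scale, which understates changes of low genes. The main values use the deposited scale. Because centring libraries on their medians moved the split of calls by far more than 10 percentage points, from 99.2% to 47.2% higher at dawn, values relative to the median gene are given beside them. Gene lists were tested with camera (preset correlation 0.01, and with an estimated correlation) and fry, adjusted over the lists within a comparison. Figures were drawn with matplotlib 3.10.9.

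Gene names need care. The reference table given for naming holds other locus tags, and 0 of the table's tags matched it. The names of 15 genes were fixed with their tags before the data were examined, from general knowledge of the strain's annotation. The tags of sasA, cikA, rbcS and opcA were fixed then within gene lists, and their symbols were written later. No source used here checks these names. Of 26 lists planned, 6 had locus tags and 3 had at least 3 tested members. Tags with B and tags with R were added as 2 lists after the table was opened and before any comparison was computed. Another 7 lists, filled from memory with runs of tags after the table was opened, were computed and their results seen; they were then left out, with the gene symbols recalled for them, because no source used here pairs those tags with genes. Adjusted p-values of lists therefore cover 5 lists, a number settled after results had been seen.

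Genes named in the text follow a rule fixed before the data were examined. It takes the 15 named genes in every comparison, list members with the smallest p where a list is described, and the genes with the largest changes whose libraries do not overlap between groups: 10 rises and 10 falls for the genotype comparisons, and 5 and 5 for the others. Of unnamed tags at most 2 that rose and 2 that fell are printed per comparison.

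The procedure was tested on simulated counts drawn from the real means and depths, with 200 genes changed, over 2539 genes. For rel- against wild type at dawn, 85 of 100 genes changed 2-fold and 100 of 100 changed 4-fold were recovered, with 11 of 2339 unchanged genes called. For the interaction these were 39 and 99 of 100, with 4 unchanged genes called. These simulations used 1 assumed dispersion for all genes and put no offset of whole libraries between replicates. In the real data the median log2 ratio of replicate 1 to replicate 2 was 0.10 and 0.36 in wild type at dawn and dusk. In rel- it was -0.28 and 0.18, so recovery and false calls in the real tests may differ. A shift of 1.87 put into whole libraries was found as 1.84. Alternatives were other pseudocounts (200 and 2), no minimum, median-centred and quantile-normalized libraries, the replicate number as a block, an intensity trend, a threshold on the change, the 2 groups alone, each library left out in turn, and, added after seeing the data, tags with R left out. Alternatives that refit the model estimate the pooling of the spread anew, so a call can change while a gene's own values do not. Without tags with R, rel kept its log2 change of -7.21 at dawn, while its limma adjusted p went from 8.44e-15 to 4.38e-152. Calls gained or lost under an alternative may thus reflect the pooling rather than the gene.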

Results

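Synechococcus elongatus PCC7942 is a unicellular cyanobacterium used to study circadian rhythms. Its rel gene encodes the enzyme that makes and breaks down the alarmone ppGpp, a nucleotide that bacteria use as a starvation signal. RNA sequencing libraries were made from wild type and from a rel- strain. Cultures were entrained by light and dark, released into constant light, and harvested at subjective dawn (circadian time 0 h) and at subjective dusk (circadian time 12 h). There were 4 groups of 2 libraries each, 8 libraries in all, and the labels ask how the rel- strain differs from wild type at each time point. The table held 2715 genes. In each library the values were whole multiples of 1 constant, and dividing by it gave 6559147 to 12376534 reads per library. The labels do not say that the 2 libraries of a group came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

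The rel gene (Synpcc7942_1377) was examined first as a check of the labels. Its value was 5224 ± 274 (SD, n = 2) in wild type at dawn and 6866 ± 1755 (SD, n = 2) in wild type at dusk. In the rel- libraries it was 8.79 and 23.6 at dawn, and 44.1 and 686 at dusk, which stand for 3, 7, 17 and 187 reads. The library labelled rel- dusk replicate 2 thus held more rel reads than the others of its strain, 187 of 7472091 reads, against 6708 of 9536329 and 4088 of 6559147 in wild type at dusk. The fitted log2 change in rel- was -7.21 ± 0.48 (SE) at dawn and -4.99 ± 0.48 (SE) at dusk. Each SE pools the spread over the 4 groups and over genes, so it does not show the wider spread at dusk. The dusk change was -6.72 without rel- dusk replicate 2 and -3.26 without rel- dusk replicate 1. Values this low depend on the pseudocount of 20: the change was -4.65 at dawn and -3.90 at dusk with a pseudocount of 200, and -8.30 and -5.24 with one of 2.

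Most values were higher in rel- than in wild type. On the deposited scale the median gene was 3.52-fold higher at dawn and 3.05-fold higher at dusk, a shift of 1.82 and 1.61 on the log2 scale. The ratio of mean reads per library, rel- to wild type, was 0.790 at dawn and 1.15 at dusk. The median value per library was 869 and 805 in wild type at dawn, 1172 and 900 in wild type at dusk, 2727 and 3371 in rel- at dawn, and 3445 and 2938 in rel- at dusk. With 2 libraries against 2, an exact permutation test cannot give a p below 0.333, so these medians are given as values. Changes below are on the deposited scale, and where a relative value is given, it is relative to the median gene, that is with libraries centred on their medians.

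**Figure D1:**
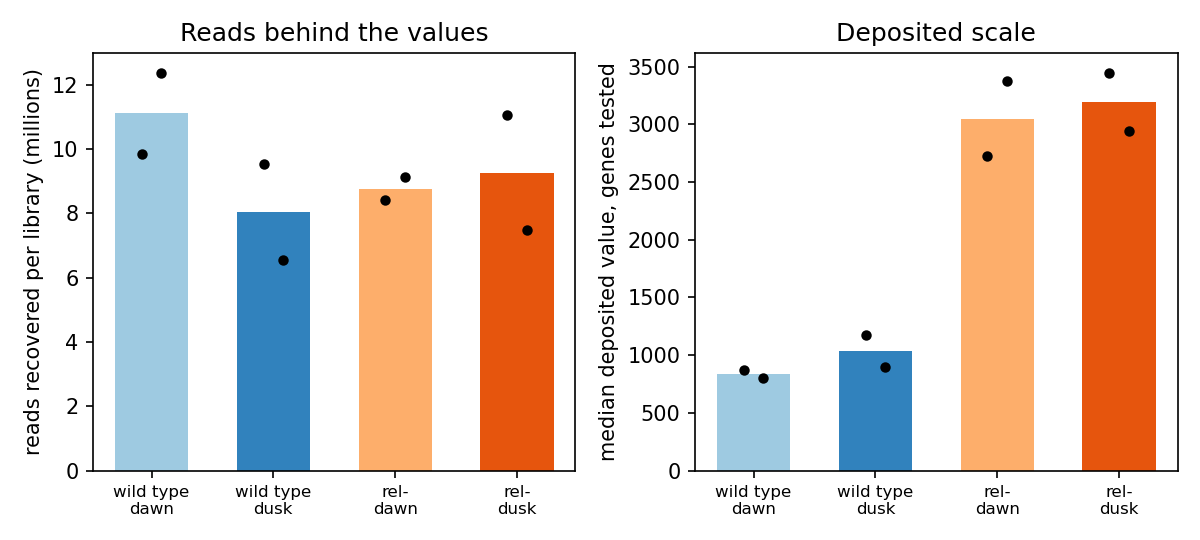
Left, reads recovered per library; right, the median deposited value over the genes tested. Bars are means of 2 libraries and points are libraries. Reads ranged from 6559147 to 12376534 with no step between strains, while the median values of the rel- libraries, 2727 to 3445, all lay above those of wild type, 805 to 1172.

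At subjective dawn the clock genes kaiA, kaiB and kaiC, which encode the circadian oscillator, were among the named genes that were higher in rel- even relative to the median gene. The kaiC value was 1714 ± 68.0 (SD, n = 2) in wild type and 27142 ± 1959 (SD, n = 2) in rel-, a 15.6-fold difference. Its log2 change was 3.97 ± 0.26 (SE) and 2.13 ± 0.15 (SE) relative to the median gene. The kaiB gene was 10.4-fold and kaiA 8.78-fold higher, with relative log2 changes of 1.54 and 1.30. The glucose-6-phosphate dehydrogenase gene zwf, which opens the oxidative pentose phosphate pathway, was 5.87-fold higher, and opcA, whose product activates that enzyme, was 5.44-fold higher. Both also passed relative to the median gene, at 0.72 and 0.61 on the log2 scale. The gnd and glgP genes, described below with zwf and opcA, were 4.48-fold and 3.79-fold higher. Neither passed relative to the median gene, at 0.33 and 0.09 on the log2 scale.

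Not every gene followed the general shift at dawn. The photosystem II gene psbAI had a log2 change of -0.10 ± 0.25 (SE), which did not pass (adjusted p = 0.688), and so lay 1.93 below the median gene, with a relative log2 change of -1.93 and an adjusted p of 1.84e-04. The purine synthesis gene purF was 1.57-fold higher on the deposited scale and lower relative to the median gene, at -1.18. Its deposited call was lost without either wild type dawn library or without rel- dawn replicate 2, with adjusted p between 0.0566 and 0.154. The response regulator gene rpaA was 2.79-fold higher and rpaB 2.87-fold higher; relative to the median gene their log2 changes were -0.35, which passed, and -0.31, which did not. The large subunit gene of RuBisCO, rbcL, was 7.92-fold higher, and its relative log2 change of 1.15 did not pass (adjusted p = 0.0698). The ribosome hibernation factor gene hpf was 1.94-fold higher, and its relative change of -0.88 did not pass (adjusted p = 0.101).

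By list, all 3 genes of the respiratory oxidase list were higher at dawn, by 3.64 to 4.09 on the log2 scale, and all 3 were also higher relative to the median gene. The list passed against other genes (camera adjusted p = 0.00266, and adjusted p = 0.334 with an estimated correlation). All 4 genes of the glycogen and oxidative pentose phosphate list and all 7 clock genes were higher on the deposited scale, over all genes and adjusted over the list alone. These lists did not pass against other genes (camera adjusted p = 0.237 and 0.106), though the clock list did under the replicate block, at 0.0360, and without either wild type dawn or either rel- dusk library. On the deposited scale fry, which asks whether the genes of a list move on balance one way, gave p of 1.54e-04 for the oxidases, 3.04e-04 for the clock genes and 0.00117 for the glycogen and pentose phosphate genes. Because 2447 of 2539 genes were higher at dawn on this scale, the fry values do not set these lists apart from other genes. Of the clock genes, 3 were higher and 1 was lower relative to the median gene. Among tags with B, a class of locus tag seen in the table, 14 of 50 were tested and all 14 were lower relative to the median gene, with a median of -1.74. On the deposited scale 5 were higher and 2 lower, and the median was 0.09, so that the sign of the median differs from that of the test (camera adjusted p = 1.64e-28, and adjusted p = 0.0275 with an estimated correlation). Tags with R, another class, had a median of 1.40 on the deposited scale and -0.44 relative to the median gene, with 26 of 33 higher on the former. Their camera adjusted p of 7.79e-12 was 0.0883 with median-centred libraries and the adjusted p was 0.334 with an estimated correlation, and without wild type dawn replicate 1 it was 0.350.

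In all, 2447 of 2539 genes were higher and 19 lower in rel- at dawn (limma, adjusted p threshold 0.05), the latter 12 without wild type dawn replicate 1. Relative to the median gene, 500 were higher and 559 lower. The calls on the deposited scale thus rest largely on the general shift between libraries. All genes of a library share that shift, and pooling the spread over genes adds no replicates of it. The files do not pair other tags with gene names; of unnamed tags, Synpcc7942_1240 was 73.3-fold and Synpcc7942_1238 31.5-fold higher, and Synpcc7942_1724 had the largest fall after rel, with a log2 change of -3.12 ± 0.28 (SE). Their log2 changes relative to the median gene, 4.36, 3.14 and -4.95, passed. With a pseudocount of 200 the deposited log2 changes were 4.88, 3.73 and -2.02.

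At subjective dusk kaiB and kaiC differed less between the strains than at dawn, with interactions of -1.66 and -2.14 that passed, while that of kaiA, -0.35, did not pass (adjusted p = 0.672). The kaiA gene was 6.89-fold higher in rel-, and its relative log2 change of 1.17 passed. The kaiC gene was 3.55-fold and kaiB 3.29-fold higher, and relative to the median gene neither passed, at 0.22 and 0.11. The histidine kinase gene cikA was 1.51-fold higher on the deposited scale and lower relative to the median gene, at -1.01. That deposited call was lost with the 2 groups alone (adjusted p = 0.0745), without either wild type dawn library, without wild type dusk replicate 2 and without rel- dusk replicate 1, where adjusted p reached 0.291. The hpf gene was 4.62-fold and purF 3.57-fold higher, and neither passed relative to the median gene, at 0.60 and 0.22.

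The 4 genes of the glycogen and oxidative pentose phosphate list did not follow the general rise at dusk. On the deposited scale zwf had a log2 change of 0.52 (adjusted p = 0.0609), glgP, the glycogen phosphorylase gene, 0.53 (adjusted p = 0.0527), opcA 0.36 and gnd, the 6-phosphogluconate dehydrogenase gene, 0.22, and none passed over all genes or adjusted over the list alone. Without wild type dusk replicate 1, zwf and opcA passed; zwf passed under a larger pseudocount, and glgP passed under a larger pseudocount, an intensity trend, without tags with R or without either rel- dawn library. Relative to the median gene all 4 were lower, at -1.09 for zwf, -1.08 for glgP, -1.25 for opcA and -1.39 for gnd. With the preset correlation the list was lower than other genes (camera adjusted p = 0.00123), and with an estimated correlation it did not pass (adjusted p = 0.305). Its median of 0.44 and mean of 0.41 on the deposited scale were above 0. The psbAI gene again did not pass on the deposited scale, at 0.26, and was lower relative to the median gene, at -1.35. The rbcL gene was 2.98-fold higher, with a relative log2 change of -0.04 that did not pass.

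The 3 respiratory oxidase genes were higher at dusk too, by 3.24 to 3.64 on the log2 scale, and all 3 relative to the median gene (camera adjusted p = 0.00845, and adjusted p = 0.305 with an estimated correlation). The 7 clock genes were all higher on the deposited scale, over all genes and adjusted over the list alone, while relative to the median gene 1 was higher and 3 were lower, and the list did not pass against other genes (camera adjusted p = 0.953). All 14 tested tags with B were lower relative to the median gene, with a median of -1.57; their deposited median was 0.04 and their mean -0.24 (camera adjusted p = 3.33e-23, and adjusted p = 0.0405 with an estimated correlation). Tags with R had a deposited median of 0.94, with 19 of 33 higher, a relative median of -0.67 and a camera adjusted p of 3.22e-09, with an adjusted p of 0.317 with an estimated correlation and 0.0541 with median-centred libraries, and without rel- dusk replicate 2 the direction turned (adjusted p = 0.898).

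At dusk 2378 genes were higher and 28 lower in rel-, and relative to the median gene 627 were higher and 620 lower. The calls on the deposited scale thus again rest largely on the general shift between libraries. The tags Synpcc7942_2107 and Synpcc7942_0840 were 56.5-fold and 49.7-fold higher, and Synpcc7942_0834 had a log2 change of -2.93 ± 0.26 (SE). Their relative log2 changes, 4.21, 4.02 and -4.54, passed. The log2 change of Synpcc7942_2107, 5.82, was 4.91 without rel- dusk replicate 2 and 6.73 without rel- dusk replicate 1, and its values in these 2 libraries were 25201 and 7148. That of Synpcc7942_0840, 5.64, rests on low values in wild type and was 2.97 with a pseudocount of 200 and 7.11 with one of 2, and with 200 that of Synpcc7942_2107 was 5.03. Dawn and dusk comparisons share no libraries. Relative to the median gene, 329 genes were higher at both times against 123 for independent lists, 317 were lower at both against 137, and 38 went opposite ways.

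**Figure D2:**
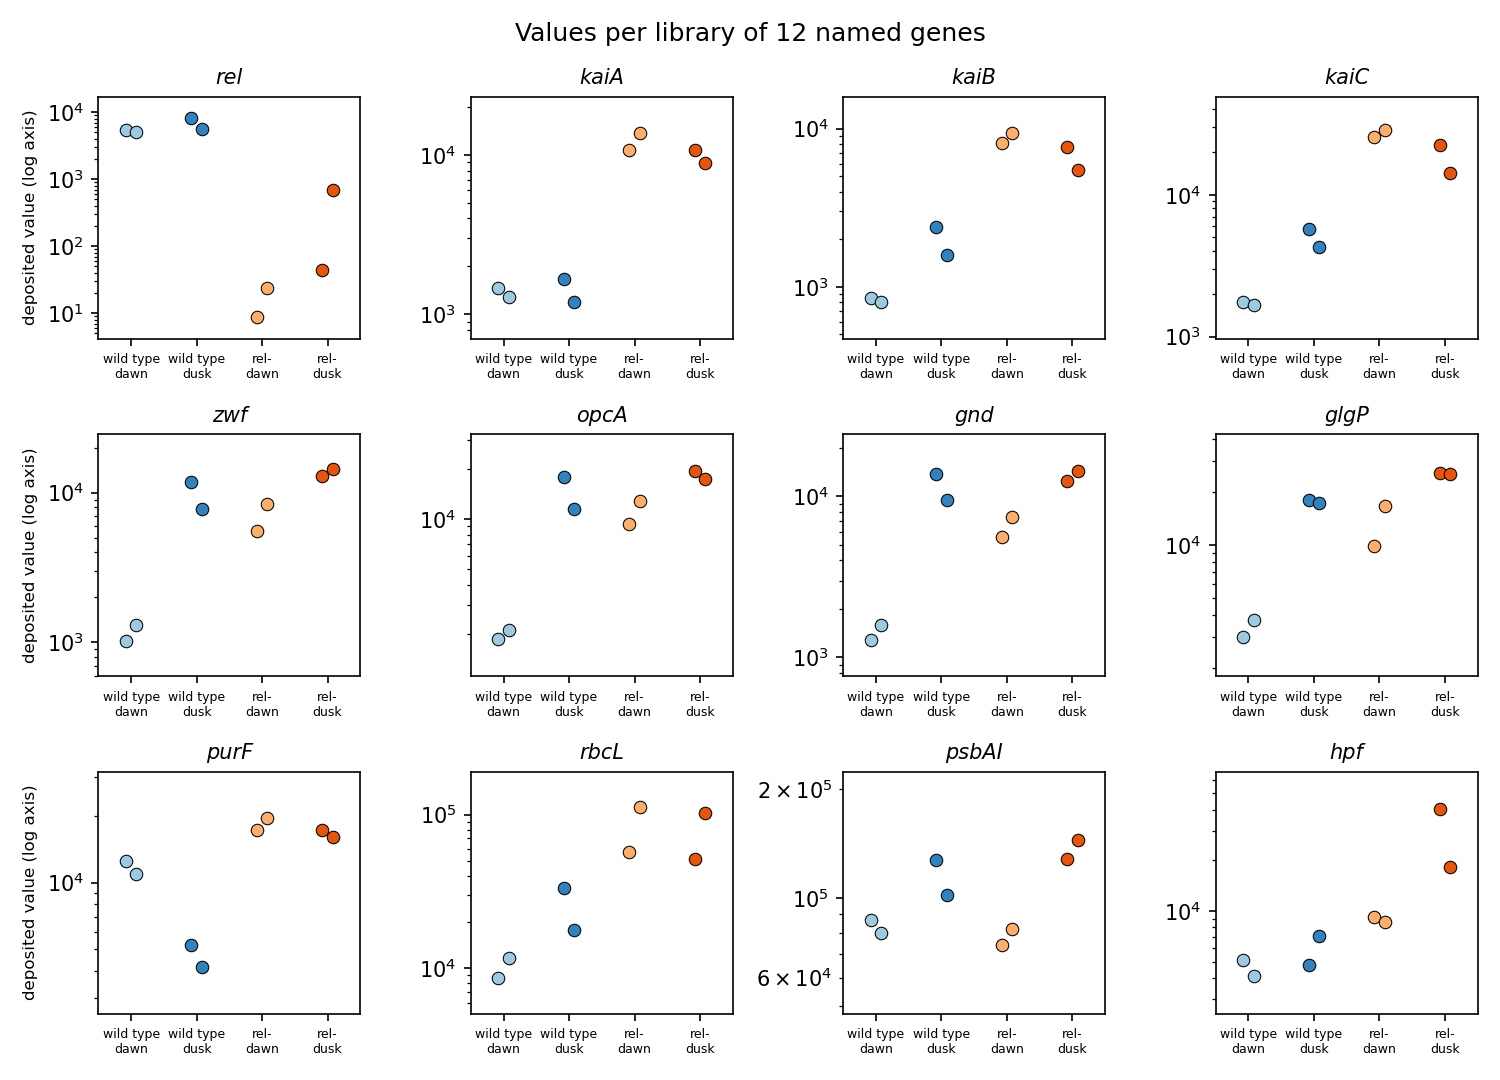
Deposited values per library (log axis) of 12 named genes in the 4 groups, 2 points per group. The kaiC values of wild type rose from dawn to dusk while those of rel- were high at both times; rel was low in the rel- libraries, with 686 in 1 dusk library.

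In wild type the genes of glycogen breakdown and the oxidative pentose phosphate pathway rose from subjective dawn to dusk. The zwf value went from 1160 ± 204 (SD, n = 2) to 9724 ± 2798 (SD, n = 2), an 8.14-fold rise, and gnd, opcA and glgP rose 7.93-fold, 7.07-fold and 5.24-fold. All 4 passed over all genes, adjusted over the list alone, and relative to the median gene (camera adjusted p = 2.44e-11 for the list, and adjusted p = 0.0954 with an estimated correlation). Their relative log2 changes were 2.10 to 2.74. The kaiC gene rose 2.89-fold, kaiB 2.34-fold and cikA 2.24-fold, and relative to the median gene they passed at 1.24, 0.94 and 0.87. The kaiB call was lost without wild type dusk replicate 1 (adjusted p = 0.0502). The kaiA, rpaA, rpaB and sasA genes did not pass, with log2 changes of 0.04, 0.28, 0.09 and 0.21, and the clock list did not pass against other genes (camera adjusted p = 0.0664), though it did with quantile normalization, at 0.0442.

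The purF gene went the other way in wild type, from 11731 ± 1068 (SD, n = 2) at dawn to 4667 ± 758 (SD, n = 2) at dusk, a log2 change of -1.33 ± 0.25 (SE) and of -1.62 relative to the median gene, which passed. The 3 respiratory oxidase genes rose by 1.34 to 1.45 (camera adjusted p = 9.93e-04, and adjusted p = 0.257 with an estimated correlation). The RuBisCO genes rbcL and rbcS rose 2.41-fold and 1.92-fold, and neither passed relative to the median gene. Without wild type dusk replicate 1 neither passed, at 0.82 and 0.39 on the log2 scale. Without wild type dawn replicate 1 neither passed (adjusted p = 0.0735 and 0.166), nor did rbcS without wild type dawn replicate 2 (adjusted p = 0.144). The psbAI and hpf genes did not pass, at 0.45 and 0.35. Of the tags with B, 4 of 14 rose over all genes; the list passed (camera adjusted p = 0.0406, and adjusted p = 0.567 with an estimated correlation) and was lost under the replicate block, at 0.0866, and without 6 of the 8 libraries in turn. No tag with R passed, and the list had a camera adjusted p of 0.198. It passed under the replicate block, at 0.0174, without wild type dawn replicate 1, at 4.67e-09, and without either rel- dusk library, at 0.0174 each.

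In wild type 310 genes rose and 14 fell, of 2539 tested. With median-centred libraries 281 rose and 380 fell. Without wild type dawn replicate 1 these were 204 and 5, without wild type dawn replicate 2 they were 171 and 6, and without wild type dusk replicate 1 they were 175 and 13, on the deposited scale. The tags Synpcc7942_1612 and Synpcc7942_1610 rose 13.4-fold and 12.4-fold, and Synpcc7942_0905 and Synpcc7942_1607 had log2 changes of -2.06 and -1.65. These 4 tags also passed relative to the median gene, at 3.45, 3.34, -2.35 and -1.94.

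In rel- the glycogen and pentose phosphate genes rose less from dawn to dusk. The gnd gene rose 2.07-fold, zwf 1.99-fold and glgP 1.99-fold, and opcA, at 0.74 on the log2 scale, did not pass over all genes (adjusted p = 0.0652) and passed adjusted over the list alone. Relative to the median gene all 4 passed, at 0.98 for gnd, 0.93 for zwf, 0.92 for glgP and 0.67 for opcA (adjusted p = 0.0187 for the last). The opcA gene also passed with quantile normalization, at 0.65 (adjusted p = 0.0284), under a larger pseudocount, without tags with R, and without either wild type dusk library or rel- dawn replicate 2. The list passed (camera adjusted p = 0.00227, and adjusted p = 0.323 with an estimated correlation). Without rel- dawn replicate 1, zwf, gnd and glgP no longer passed, with adjusted p of 0.235, 0.114 and 0.285. None of the 7 clock genes passed on the deposited scale; kaiC was at -0.61, kaiB at -0.43 and kaiA at -0.31. Without rel- dusk replicate 1, kaiC passed at -0.93 (adjusted p = 0.0458). Relative to the median gene these 3 and rpaB were lower at dusk, at -0.68, -0.50, -0.38 and -0.45. The clock list had a camera adjusted p of 0.147, and of 0.0463 with quantile normalization.

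The hpf gene rose 3.04-fold in rel- and psbAI 1.75-fold, and both passed relative to the median gene, at 1.54 and 0.74. The psbAI call (adjusted p = 0.0308) was lost under the replicate block, at 0.0679, with the 2 groups alone, at 0.119, and without either wild type dawn library or any rel- library. The purF and rbcL genes did not pass, at -0.15 and -0.14. The 3 respiratory oxidase genes rose by 0.83 to 1.28 (camera adjusted p = 0.00227, and adjusted p = 0.323 with an estimated correlation). The rel gene itself rose 6.01-fold, a log2 change of 2.59. Without rel- dusk replicate 2 it was 0.86 and did not pass, without rel- dusk replicate 1 it was 4.32, with a pseudocount of 200 it was 1.11 and with one of 2 it was 3.42, and it did not pass with median-centred libraries, at 2.52 (adjusted p = 0.105), or quantile normalization, at 1.66 (adjusted p = 0.216). Tags with B and tags with R did not pass, both with a camera adjusted p of 0.253; without any 1 of the rel- libraries tags with R passed, upward in 2 cases and downward in 2.

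In rel- 184 genes rose and 66 fell, and with median-centred libraries 295 rose and 326 fell. On the deposited scale 87 rose and 53 fell without rel- dawn replicate 1, 187 and 15 without rel- dawn replicate 2, 212 and 35 without rel- dusk replicate 2, and 129 and 33 without either wild type dawn library. Synpcc7942_1987 and Synpcc7942_1849 rose 7.30-fold and 6.09-fold, and Synpcc7942_2529 and Synpcc7942_2425 had log2 changes of -1.84 and -1.66. All 4 passed relative to the median gene, at 2.80, 2.54, -1.90 and -1.73.

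The time changes of both strains, which share no libraries, were then compared. There were 108 genes that rose in both, against 22.5 for independent lists, 0 that fell in both (at most 14 could, and independent lists give 0.364) and 6 that went opposite ways. With median-centred libraries 129 rose and 59 fell in both, against 32.6 and 48.8, and 33 went opposite ways. Across the 2539 genes, which are not independent replicates, Pearson's r was 0.40 and Spearman's rho 0.26, each with a permutation p of 1e-04, the smallest that 10000 permutations can give. The 108 genes were 56 without rel- dawn replicate 1, and 69 and 61 without wild type dawn replicates 1 and 2.

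**Figure D3:**
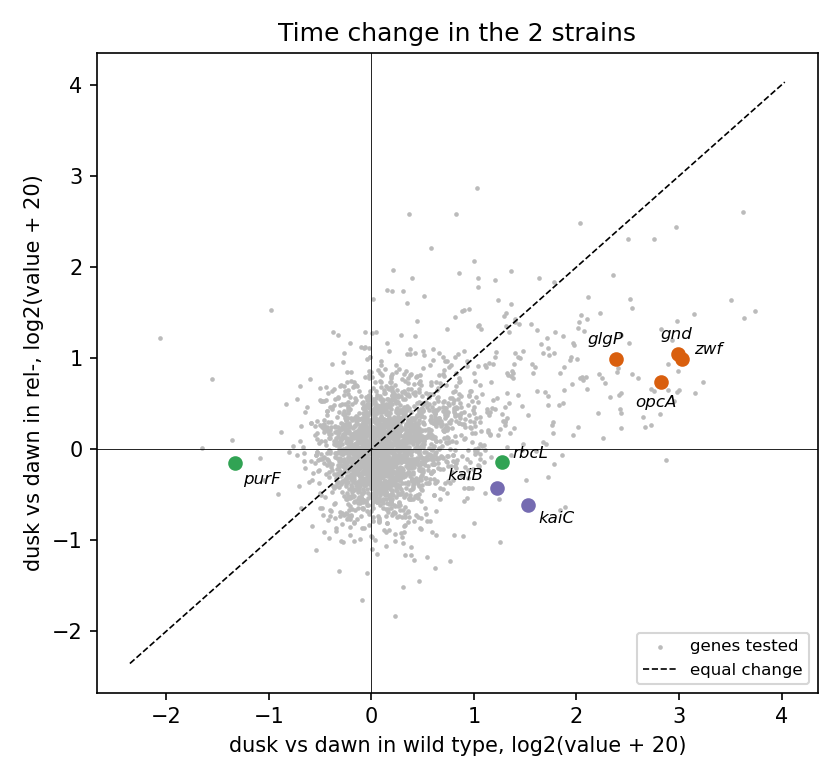
Change from subjective dawn to dusk in wild type (x axis) and rel- (y axis), on the log2(value + 20) scale, for 2539 genes; the dashed line marks equal change. The genes zwf, opcA, gnd and glgP changed by 2.39 to 3.03 in wild type and by 0.74 to 1.05 in rel-, and kaiC by 1.53 and -0.61.

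The difference between strains in the time change was tested as an interaction, the genotype effect at dusk minus that at dawn. The kaiC gene had an interaction of -2.14 ± 0.37 (SE) and kaiB of -1.66 ± 0.37 (SE), with adjusted p of 1.63e-04 and 0.00281, and both passed relative to the median gene, at -1.92 and -1.44. The cikA gene, at -0.99, did not pass (adjusted p = 0.0990), and passed with median-centred libraries, at -0.77, with quantile normalization, and without wild type dusk replicate 2 or rel- dusk replicate 1. The opcA, zwf, gnd and glgP genes had -2.08, -2.03, -1.94 and -1.39, and all 4 passed over all genes, adjusted over the list alone and relative to the median gene. The glgP call was lost without either wild type dawn library, without wild type dusk replicate 1 and without rel- dawn replicate 2, with adjusted p up to 0.225. The glycogen and pentose phosphate list passed (camera adjusted p = 1.46e-06, and adjusted p = 0.240 with an estimated correlation), as did the clock list (camera adjusted p = 0.00785, and adjusted p = 0.690 with an estimated correlation). Of the clock list 2 genes passed over all genes and 3 adjusted over the list alone. The respiratory oxidase list, tags with B and tags with R did not pass, with camera adjusted p of 0.718, 0.718 and 0.932.

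The purF gene had an interaction of 1.18 (adjusted p = 0.0319), lost under the replicate block, at 0.0731, and without 6 of the 8 libraries in turn. The rbcS interaction of -1.47 (adjusted p = 0.0243) did not pass relative to the median gene and was lost without either wild type dawn library, without wild type dusk replicate 1 and without rel- dawn replicate 2. The rbcL gene, at -1.41, did not pass (adjusted p = 0.0511) and passed under the replicate block, at 0.0183, an intensity trend, without tags with R, and without 4 of the 8 libraries in turn. The hpf gene, at 1.25, did not pass (adjusted p = 0.0587), and passed under an intensity trend, without tags with R, and without wild type dusk replicate 2 or rel- dusk replicate 2. In all 33 genes had a positive and 125 a negative interaction, and with median-centred libraries 231 and 187. On the deposited scale these were 9 and 58 without wild type dawn replicate 1, 13 and 67 without wild type dawn replicate 2, 29 and 56 without wild type dusk replicate 1, 21 and 163 without rel- dawn replicate 1, and 25 and 60 without rel- dawn replicate 2. Synpcc7942_0905 and Synpcc7942_2503 had interactions of 3.29 and 2.51, and Synpcc7942_2590 and Synpcc7942_2267 of -3.00 and -2.53. With median-centred libraries these were 3.51, 2.73, -2.77 and -2.31, and passed.

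The 3 psbA genes are related in sequence, and how reads were assigned among them is not given in the sources used here, so their values are uncertain. The mean value of psbAI was 103106, of psbAIII 236 and of psbAII 100.1, the last under the minimum for testing. The psbAIII gene was 2.36-fold and 3.84-fold higher in rel- at dawn and dusk, and its relative log2 changes of -0.60 and 0.33 did not pass. With a pseudocount of 200 its log2 change at dusk, 1.94, was 1.03.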

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

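The tests of depth, abundant tags, constants, mixing, scale and single libraries in this part were chosen only after the results they bear on were seen. The interaction test marked results whose genotype effect differed between dawn and dusk. It called 158 genes. Among named genes the log2 differences were 2.22 for rel, -1.66 for kaiB, -2.14 for kaiC, 1.18 for purF, -1.47 for rbcS, -2.03 for zwf, -2.08 for opcA, -1.94 for gnd and -1.39 for glgP. Among unnamed tags they were 3.29 for Synpcc7942_0905, 2.51 for Synpcc7942_2503, -3.00 for Synpcc7942_2590 and -2.53 for Synpcc7942_2267. With the preset correlation of 0.01 the glycogen and oxidative pentose phosphate list (camera adjusted p = 1.46e-06) and the circadian clock list (camera adjusted p = 0.00785) passed. The correlation estimated from the data was 0.81 for each list. With it neither passed (camera adjusted p = 0.240 and 0.690), so whether they differ as lists depends on this setting.

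The negative interaction of kaiB, kaiC, zwf, opcA, gnd and glgP was weighed against technical explanations. In rel- zwf, opcA, gnd and glgP rose less at dusk than in wild type. The kaiB and kaiC genes did not rise in rel-, at -0.50 and -0.68 relative to the median gene. The 6 genes were picked because they had passed this interaction. The refits therefore speak only for these genes, and passing in them is partly built in. With median-centred libraries 6 of these 6 genes kept a negative interaction past the threshold, which argues against the scale of the libraries as its cause. With each library left out in turn at least 5 of the 6 kept it, glgP being the one lost without either wild type dawn library, wild type dusk replicate 1 or rel- dawn replicate 2, so 1 library does not carry the pattern. Strain, as the labels give it, remains open as a biological explanation, and may act through the clock or otherwise; nothing here tests the route.

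Values were higher in rel- at both times. Reads per library in rel- were 0.942 of those in wild type over both times, 0.790 at dawn and 1.15 at dusk, which argues against sequencing depth as the cause of median values 3.52-fold and 3.05-fold higher. The smaller share of the most abundant tag leaves more reads for other genes by 0.16 at dawn and 0.12 at dusk on the log2 scale, against median changes of 1.82 and 1.61, which argues against it as the whole cause. The constants by which the deposited values differ from whole reads differed by 1.87 on the log2 scale at dawn and by 1.26 at dusk, and reads scaled to equal library totals changed by a median of 0.31 and 0.18. Whether these constants reflect more RNA per cell, or the amount of standard or of cells that went into each extraction, cannot be told apart, because all 4 rel- libraries carry higher constants than all 4 of wild type.

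The library rel- dusk replicate 2 held 187 rel reads against 3, 7 and 17 in the others of its strain, and the interaction of rel, 2.22 (adjusted p = 0.0432), was 0.49 without it and 3.95 without rel- dusk replicate 1. That call was also lost without either wild type dusk library (adjusted p = 0.244 and 0.246), without rel- dawn replicate 1 (adjusted p = 0.0584), with a pseudocount of 200 (0.75, adjusted p = 0.478), with no minimum (adjusted p = 0.0987), and with median-centred or quantile-normalized libraries (adjusted p = 0.266 and 0.467). If wild-type RNA had been mixed in, rel implies a share of 3.54% of reads, and 7 other genes at least 8 times lower in rel- at dawn relative to the median gene would then be higher in this library than in replicate 1, by a median of 0.52 on the log2 scale. Their observed ratios ran from -0.41 to 0.63 with a median of -0.23. The median over genes of observed minus predicted was -0.54, with a standard error of 0.17 over these 7 genes. The 7 genes come from the same pair of libraries and are not independent replicates. Log2 ratios between the rel- dusk libraries had an SD of 0.45 over the genes tested. The test thus cannot decide on mixing. No biological explanation was tested, as the design gives no group for it.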

How the results depend on the processing

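The alternative without tags with R was chosen after the data were seen; the others were fixed before the data were examined. With median-centred libraries 1059 genes passed for rel- against wild type at dawn and 1247 at dusk, 661 for dusk against dawn in wild type, 621 in rel-, 418 for the interaction, and 188 for genes changed alike in both strains. With quantile normalization these were 1054, 1244, 638, 631, 392 and 189. Both remove the general shift by construction, and the cause of the higher counts for the time comparisons was not tested. Named genes whose sign turned with median-centred libraries at dawn were hpf (-0.88), rpaA (-0.35), rpaB (-0.31), cikA (-0.24), purF (-1.18) and psbAIII (-0.60), and with quantile normalization they were at -0.81, -0.31, -0.22, -0.25, -1.21 and -0.53. At dusk these were rpaA (-0.34), rpaB (-0.57), cikA (-1.01), rbcL (-0.037), rbcS (-0.51), psbAI (-1.35), zwf (-1.09), opcA (-1.25), gnd (-1.39) and glgP (-1.08), and with quantile normalization -0.48, -0.69, -1.13, -0.19, -0.69, -1.24, -1.24, -1.35, -1.57 and -1.24, where sasA was at -0.041 as well. For dusk against dawn in rel-, a change of at least 1 on the log2 scale left 136 genes, and the 2 groups alone gave 161, with fewer libraries in the fit. With an estimated correlation, 1 list passed at dawn and 1 at dusk between strains, 0 for time in wild type and 0 for time in rel-, against 3, 4, 3 and 2. For the interaction 0 lists passed with an estimated correlation, against 2 with the preset one.

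Replicate numbers were not taken as pairs, since no label ties them and deviations of same-numbered libraries correlated between -0.20 and 0.39. With the replicate number as a block 2461, 2393, 304, 201 and 130 genes passed in the 5 comparisons, and 93 changed alike in both strains. With each library left out in turn, a group left with 1 library is assumed to vary like the others. The ranges were 2396 to 2472 genes for dawn between strains, 2246 to 2412 for dusk, 177 to 388 for time in wild type, 140 to 292 for time in rel-, 67 to 218 for the interaction and 56 to 124 for genes changed alike. The lists past the threshold numbered 3 to 4, 3 to 4, 2 to 3 and 2 to 3. The median shift was 1.66 to 1.97 at dawn and 1.44 to 1.78 at dusk, and rel changed by -7.51 to -6.91 and -6.72 to -3.26. With 1 library left out, adjusted p for tags with R ran from 8.45e-19 to 0.350 between strains at dawn, from 7.42e-13 to 0.898 at dusk, from 4.67e-09 to 0.741 for time in wild type and from 2.54e-16 to 0.501 for time in rel-. Their direction turned between strains at dusk without rel- dusk replicate 2 (adjusted p = 0.898), and for time in rel- without rel- dawn replicate 1 (adjusted p = 0.0207) or rel- dusk replicate 1 (adjusted p = 3.88e-05). Without tags with R 2443, 2386, 353, 293 and 186 genes passed. There the rbcL interaction passed (limma adjusted p = 0.00466) at the same -1.41 as in the main fit. As the values of rbcL were unchanged, that pass came from the other genes in the fit. Of the values of single genes, 854 under other alternatives kept their direction and side of the threshold, 33 turned, 37 fell short of the threshold and 26 came past it; with 1 library left out these were 806, 0, 42 and 16. Of the values of lists, 61 were kept, 15 fell short and 4 came past it, and with 1 library left out 141 were kept, 3 turned, 7 fell short and 9 came past it. The planned count-based alternative was not run, as the columns were by choice not treated as counts. Depth limits low genes such as rel in rel- and psbAII.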

Other observations

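One test in this part was set up before its result was seen, that of rel- at dawn against wild type at dusk, although values of single genes such as kaiC and zwf had been seen; the tests of the size of the dusk rise, with genes picked in either strain, were chosen after related results were seen.

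In rel- at dawn, kaiB, kaiC, zwf and opcA were higher relative to the median gene, as they were in wild type at dusk. The cikA, gnd and glgP genes also rose in wild type, and in rel- at dawn they did not pass, at -0.24, 0.33 and 0.09. A hypothesis was that rel- at dawn resembles wild type at dusk across the genome. To avoid a shared control, each change was set against its own wild type dawn library, in both ways. Across 2539 genes, which are not independent replicates, the correlations were 0.027 and 0.056 (Spearman 0.041 and 0.057). The likeness of kaiB, kaiC, zwf and opcA thus did not extend to genes in general, and the hypothesis failed the test set for it. Of these genes 2215 had no called time change in wild type, and the 310 that rose there were not examined alone. A likeness limited to genes that rise at dusk was therefore not tested.

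A second hypothesis was that the rise from dawn to dusk is smaller in rel-. The 177 genes that rose at least 2-fold above the median gene in the replicate 1 libraries of wild type were measured in the replicate 2 libraries, where their median relative rise was 1.55 on the log2 scale. In rel- it was 0.69, a ratio of 0.443, and 91.5% of the genes rose less in rel-. Picked in replicate 2 instead, 174 genes gave a ratio of 0.450, and 85.1% rose less in rel-. Genes picked for rising in wild type can give a low ratio even if rel- has as many rising genes of its own, so the converse was measured. Of genes picked in the replicate 1 libraries of rel-, 150 had a median rise of 0.91 in the replicate 2 libraries of rel- and of 0.89 in wild type, a ratio of 0.976, and 36% of them rose less in wild type. The 128 picked in replicate 2 gave a ratio of 0.613, and 58.6% rose less in wild type. The number of genes that rose depended on the scale, with 184 in rel- and 310 in wild type on the deposited scale, 295 and 281 with median-centred libraries, and 90 and 141 of these last by over 2-fold. A generally smaller dusk rise in rel- thus cannot be told apart from a partly different set of rising genes, because the sets picked in rel- went both ways. Most genes of the first set rose more in wild type and most of the second rose less, and neither median was higher in wild type.

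The most abundant tag, Synpcc7942_R0017, a tag with R, made up 22.1% and 20.9% of the total in wild type at dawn, 16.6% and 17.1% in wild type at dusk, 13.1% and 12.0% in rel- at dawn, and 9.73% and 9.59% in rel- at dusk. The other tags with R together made up 3.83%, 2.85%, 4.10% and 3.81% in the wild type libraries and 2.56%, 3.01%, 4.37% and 2.78% in those of rel-, in the same order, which overlap between strains and times. The first tag was singled out after its values were seen.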
